A study of Mus musculus with 8 samples.

How the data were processed

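Data were 2 deposited tables, each holding coverage profiles for 1 control and 1 Psat1cKO library of H3K27me3 CUT&RUN in primary mouse myoblasts. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie and Picard 2.22.2 and the mouse build mm10 were used; the order and settings of these steps, the version of Bowtie and the program that made the profiles are not given in the sources used here. The deposited values are a signal, coverage per library at 101 points of each gene, and no value is negative. The authors' scaling is not stated, but 90.9 to 92.4% of the values above 0.01 in each library were whole multiples of 1 step (tolerance 0.02 of a step), from 0.0907 to 0.115, as coverage scaled to library depth would give. Coverage is not a count of reads, so no count model was used. Tables for the IgG libraries were not analysed here, so no background was measured with a control antibody.

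The number of a table was taken as the replicate number in the sample labels, and the blocks within a table as the genotypes they are titled with. Nothing in the labels says whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The place of the points was inferred from the values: neighbouring points were equal in 27.3% of cases between points 22 and 80 for the shortest genes, against 12.8% in points 1 to 20 and 12.6% in points 82 to 101, which places the gene body, stretched to a fixed number of points, at points 21 to 81. The width of the flanks in base pairs is not given in the sources used here. Of the 273 genes, 270 were matched by transcript accession and 3 by symbol to the RefSeq annotation of GRCm38.p6, the assembly of mm10, from which coordinates (counted from 1) were taken. Genes with near-identical copies, such as Entpd4 (listed at 0 in all 4 libraries), Prl2c2 and Tmem254b, are uncertain and are not interpreted.

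The value of a gene was the sum over its 101 points, and text values of signal are the mean over these points. The test, filter, pseudocount and gene lists were fixed before the data were examined, for several possible units. The choice of the sum rather than the mean under the pseudocount was not, and was made after trial fits with several pseudocounts, filters and the block had been seen; the result with the mean is given with the alternatives. Genes with a sum above 2.35, the lower quartile of all values, in at least 2 libraries were kept (218 genes), and limma 3.58.1 in R 4.3.3 was fitted with a variance trend to log2(sum + 1), knockout against control, without a replicate term, with Benjamini-Hochberg adjustment at 0.05. Log2 changes are on that scale and understate the change of genes with low signal. Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated one, with fry, and with two-sided Fisher's exact tests of higher against lower members. Lists with at least 3 tested genes entered camera and fry. Adjusted p-values of camera and fry are over the 5 such lists, and those of Fisher's exact tests over all lists with a tested gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

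The fit was tested on simulated data with the real means and replicate differences, in 20 simulations of 218 genes with 40 of them altered. The spread of each gene was taken from the fit with a replicate block and shuffled between genes, and errors were independent between genes. The simulated data therefore lack the link of spread to signal and the correlation between genes. The fit without a replicate term made 0 false calls per simulation, recovering the shares given with the results; with the replicate number as a block it recovered 69.8% of genes with a log2 change of 1 and 94.0% of those with a log2 change of 2, with 2 false calls per simulation.

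Genes were named by a rule fixed in advance: every represented member of the lists of serine metabolism, myogenic regulators, cell cycle inhibitors and Polycomb, the 10 highest and 10 lowest changes past the threshold with the same direction in both replicates, passing over predicted genes, and up to 4 members of each other list past the threshold. As nothing passed, the rule gave only Pax7, Myf5 and Myf6, and all other genes were chosen after their values were seen. A few genes of these groups are not reported here, though the counts include them. Alternatives were other pseudocounts and filters, quantile normalization, the replicate block, each library left out, strong-signal genes, the region around the start, exclusion of the sex chromosomes and a stricter threshold; alternatives with the mean over points, subtracted background, the single Pax7 point removed (with all libraries, without control replicate 2, and with the mean and the block), and the block without sex chromosomes were added after seeing the data.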

Results

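H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb complexes place over silenced genes, was profiled by CUT&RUN, in which an antibody guides a nuclease to release the DNA around a mark. The cells were primary myoblasts from mouse hindlimb muscle. Control cells had floxed Psat1 alleles and no Cre at Pax7, and knockout cells (Psat1cKO) had the same floxed alleles with a heterozygous Pax7 Cre. Psat1 encodes phosphoserine aminotransferase, an enzyme of serine synthesis that also yields alpha-ketoglutarate, a cofactor of the demethylases that remove H3K27me3. The series comprised 8 samples, of which 4 were H3K27me3 libraries, 2 per genotype, and the other 4, with non-specific IgG, were not analysed here. The tables gave coverage profiles, each a fixed number of points along a gene and its flanks, for 273 genes in each H3K27me3 library, 220 genes under the heading UP and 53 under the heading DOWN in Psat1cKO. How these genes were chosen is not given in the sources used here, so the lists are not taken as independent evidence of any direction. Psat1 itself was not among the 273 genes, so the knockout could not be checked in these values.

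If the values are coverage per 1000000 reads, the size of their smallest step put the depth, rounded to 3 digits, at 11000000 reads for control replicate 1, 8700000 for control replicate 2, 9430000 for knockout replicate 1 and 8930000 for knockout replicate 2. At that depth the median gene was covered by 48.9 to 71.2 reads summed over the points of its profile, counting a read at every point it covers. Signal was highest around the transcription start and lower along the gene body. On the UP list, for example, the mean signal of control replicate 1 was 0.265 at its highest point, point 22, and 0.116 over points 41 to 61. Across the 273 genes, libraries with the same replicate number resembled each other more than libraries of the same genotype. Spearman's rho was 0.948 between control and knockout replicate 1 and 0.970 between control and knockout replicate 2, against 0.891 between the control libraries and 0.887 between the knockout libraries. These are correlations across genes, which are not independent replicates.

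**Figure D1:**
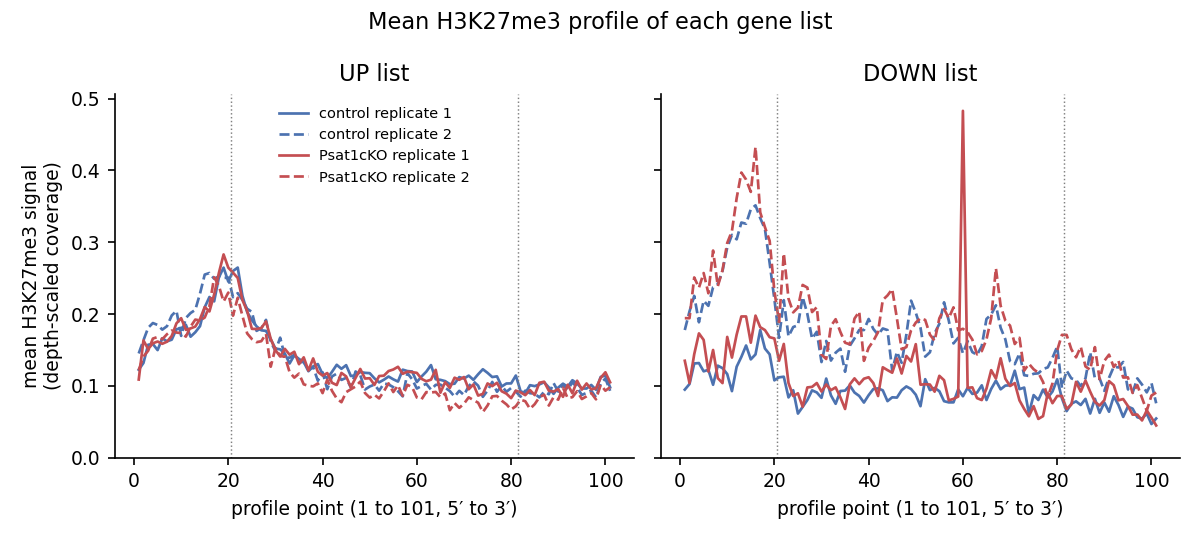
Mean H3K27me3 signal (vertical axis, depth-scaled coverage) at each profile point (horizontal axis, from 5′ to 3′) over the UP and DOWN lists, 1 line per library; dotted lines mark the inferred gene start and end. The DOWN list separates by replicate (dashed lines above solid lines), and its peak of 0.483 at point 60 in knockout replicate 1 comes from a single point of Pax7.

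The first comparison asked whether the level of H3K27me3 over the listed genes differs between knockout and control myoblasts. Over the UP list, mean signal per point was 0.134 ± 0.0021 (SD, n = 2) in control and 0.125 ± 0.012 (SD, n = 2) in knockout cells, a knockout to control ratio of 0.984 in replicate 1 and 0.878 in replicate 2. Over the DOWN list it was 0.133 ± 0.056 (SD, n = 2) in control and 0.150 ± 0.056 (SD, n = 2) in knockout cells, with ratios of 1.18 and 1.10. Without Pax7, the mean of the DOWN list was 0.0947 in control and 0.107 in knockout replicate 1, and 0.169 and 0.184 in replicate 2. The difference between genotypes on the DOWN list was smaller than the spread between replicates, since replicate 2 was 1.85 times replicate 1 in control and 1.72 times in knockout cells. With 2 libraries per genotype the exact permutation test cannot give a two-sided p below 0.333. Over the 218 genes with enough signal to test, the median log2 change was -0.04, with 0.06 in replicate 1 and -0.15 in replicate 2. Values scaled to depth cannot show a shift of the whole genome.

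No gene passed limma at an adjusted p below 0.05 (0 higher and 0 lower of 218 genes; smallest adjusted p = 0.999), and 1 gene was higher and 0 were lower at an unadjusted p below 0.05. The count was 0 as well when adjusted over the UP list alone (178 genes) or over the DOWN list alone (40 genes). In simulated data with spreads shuffled between genes, this fit recovered 1.25% of genes with a log2 change of 1 and 14.5% of those with a log2 change of 2. Leaving out control replicate 2 brought 1 gene past the threshold, Pax7 (log2 change 3.17, adjusted p = 0.00234, limma), set against control replicate 1 alone, in which its signal was far lower (control replicate 2 was 10.7 times replicate 1). That value includes a single extreme point of Pax7 in knockout replicate 1; without the point the log2 change was 2.33 and the call was lost (adjusted p = 0.893, limma). Over the libraries left out in turn, the log2 change of Pax7 ranged from 0.09 to 3.17. A fit without 1 library sets both replicates of 1 genotype against a single replicate of the other. Here and below, values with a library left out therefore also carry the difference between replicates.

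By direction alone, more genes of the DOWN list were higher than lower in knockout cells in both replicates (30 and 25 of 40 higher), whereas on the UP list more genes were lower only in replicate 2 (132 of 178 lower, against 83 in replicate 1). Over both replicates, of the 40 DOWN genes tested, 27 were higher and 13 lower (mean log2 change 0.16), and of the 178 UP genes 65 were higher and 113 lower (mean -0.07). Without knockout replicate 2, 114 UP genes were higher and 63 lower, and 14 DOWN genes were higher and 25 lower. Of the DOWN genes, 10 were higher and 29 lower without control replicate 1. The DOWN counts were 31 higher and 7 lower without control replicate 2, and 32 and 6 without knockout replicate 1. The difference between the list means was 0.21 in replicate 1 and 0.26 in replicate 2, and 0.23 over both. With a preset correlation of 0.01 between genes, camera gave p = 6.22e-05 for the DOWN list against all other genes tested, which are the UP list, but with an estimated correlation the call was lost (p = 0.367). fry, which asks whether a list moves one way by itself, gave p = 0.830 for DOWN and p = 0.785 for UP. Without control replicate 1 the difference between the lists was -0.25, and without knockout replicate 2 it was -0.30, the opposite direction. It was 0.75 without control replicate 2 and 0.80 without knockout replicate 1. These values, and the counts without 1 library, also carry the difference between replicates, in which the lists differed. Changes taken within a replicate, which gave 0.21 and 0.26, do not carry it.

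**Figure D2:**
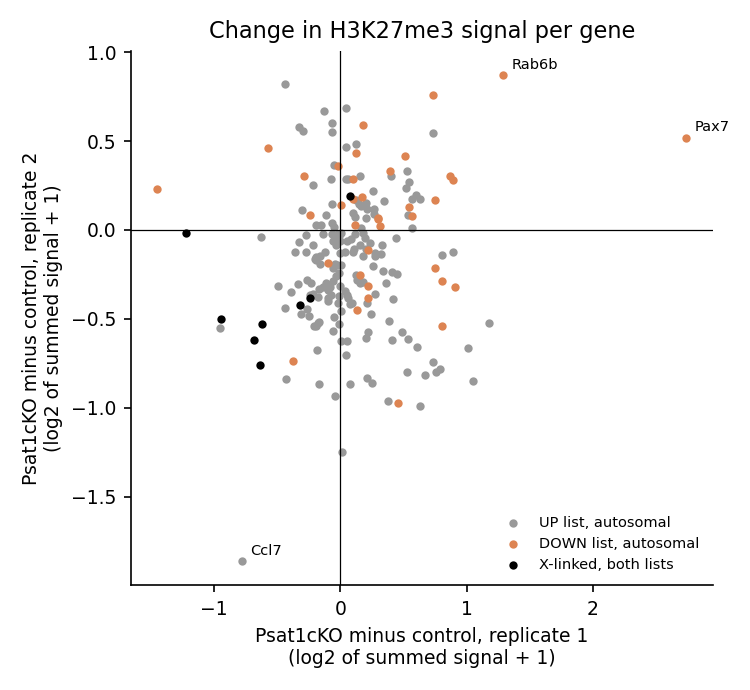
Knockout minus control difference in log2(summed signal + 1) for each of the 218 genes tested, replicate 1 on the horizontal and replicate 2 on the vertical axis, 1 dot per gene. Pax7 and Rab6b lie in the upper right, and 7 of the 8 X-linked genes lie below 0 in both replicates.

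The second comparison was between the replicates. Of 218 genes, 122 (56%, exact 95% interval 49.1 to 62.7%) differed between the genotypes in the same direction in both replicates, against 47.4% for independent directions. The interval takes genes as independent, which they are not, and does not measure the spread between replicates. Spearman's rho was 0.09 and Pearson's r 0.11 across genes, and r was 0.32 with a pseudocount of 10 and 0.04 with a pseudocount of 0.1. Genes lower in both knockout libraries numbered 72, against 62.7 for independent directions, and genes higher in both numbered 50, against 40.7. Among the 137 genes above the median signal, 65% had the same direction, against 49.9% for independent directions, with a rho of 0.35; on the DOWN list above the median signal the share was 68.8%, against 59.6%, with a rho of 0.17. On the UP list the share was 63.8% (rho 0.34) above the median signal and 41.1% (rho -0.23) below it, against 53.1% and 42.3% for independent directions.

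Among the lists of genes fixed before the data were examined, the myogenic regulators were represented by Pax7, Myf5 and Myf6, all on the DOWN list. Pax7, the transcription factor of muscle stem cells (chromosome 4, 139737059 to 139833530, minus strand), had a mean signal of 0.195 ± 0.229 (SD, n = 2) in control and 0.397 ± 0.168 (SD, n = 2) in knockout cells, and its log2 change was 1.63 ± 0.82 (SE; limma adjusted p = 0.999). A single point, point 60 in knockout replicate 1, held 74.1% of that library's Pax7 signal. Without it the knockout to control ratio of Pax7 was 2.29 in replicate 1 and 1.46 in replicate 2. The knockout cells carry Cre at 1 of their Pax7 alleles by genotype, so this locus differs between the groups by construction. Myf5, a determination factor of the muscle lineage (chromosome 10, 107482908 to 107486927), had 0.061 ± 0.063 in control and 0.053 ± 0.048 in knockout cells (SD, n = 2 each; log2 change -0.05 ± 0.80, SE). Its neighbour Myf6, also a myogenic transcription factor (chromosome 10, 107492848 to 107494723), had a log2 change of -0.61 ± 0.90 (SE) and went in opposite directions in the replicates, with knockout to control ratios of 0.237 and 1.18. Leaving out 1 library gave log2 changes from -1.12 to 0.82 for Myf5 and from -2.16 to 0.95 for Myf6. The list's mean change was 0.32 and its median -0.05, and it did not pass camera (adjusted p = 0.312; adjusted p = 0.592 with an estimated correlation). Without point 60 of Pax7 the mean change was 0.03 (camera unadjusted p = 0.749). The list's mean change was -0.79 without control replicate 1 and 1.28 without knockout replicate 1. Replicate 2 exceeded replicate 1 for these genes by a median log2 difference of 2.14 in control and 1.73 in knockout cells. The opposite directions therefore carry that difference and do not measure the genotype alone.

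**Figure D3:**
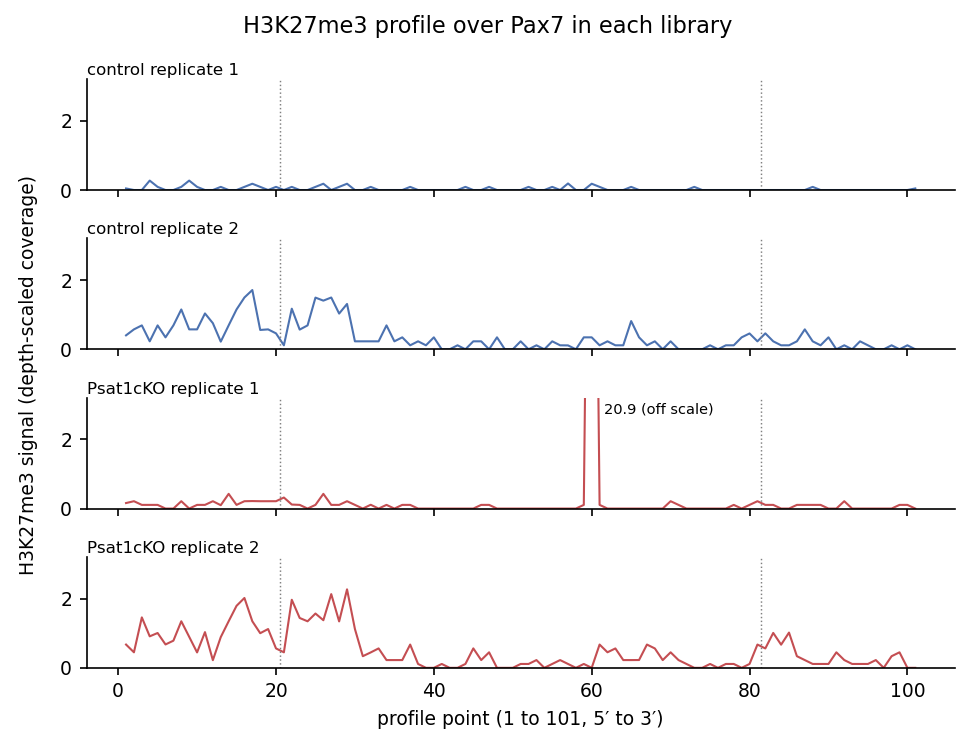
H3K27me3 signal (vertical axis, depth-scaled coverage) at each point of the Pax7 profile (horizontal axis, from 5′ to 3′) in each library; dotted lines mark the inferred gene start and end. The value of 20.9 at point 60 in knockout replicate 1 is off the axis, which stops at 3.2, and signal in points 1 to 30 is higher in both replicate 2 libraries.

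Genes of muscle structure were represented by Myh4, a fast myosin heavy chain, Ckm, the muscle creatine kinase, and Atp2a1, the fast-fibre calcium pump, again all on the DOWN list. Their mean log2 changes over both replicates were 0.17 ± 0.37, 0.18 ± 0.43 and 0.01 ± 0.70 (SE), none past limma. Only Ckm was higher in knockout cells in both replicates: in replicate 1 the knockout to control ratio was 0.990 for Myh4 and 0.767 for Atp2a1. Without knockout replicate 2, 0 of the 3 were higher (mean change -0.43), and without control replicate 1, 1 was (mean change -0.26), whereas all 3 were higher without control replicate 2 (mean change 0.51) and without knockout replicate 1 (mean change 0.67). Atp2a1 was lower over both replicates after quantile normalization, with background subtracted or with a pseudocount of 0.1. Ckm (chromosome 7, 19411094 to 19421583) had 0.224 ± 0.088 in control and 0.255 ± 0.101 in knockout cells (SD, n = 2 each), with a knockout to control ratio of 1.14 in each replicate.

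All other represented lists came from the UP list. In the list of Notch, Wnt and quiescence genes, Wnt5a, a secreted Wnt ligand, Dkk2, a Wnt antagonist, and Jag1, a Notch ligand, were lower in knockout cells, with log2 changes of -0.30 ± 0.27, -0.32 ± 0.40 and -0.17 ± 0.68 (SE). The list did not pass camera (adjusted p = 0.312, and 0.592 with an estimated correlation). Wnt5a (chromosome 14, 28504543 to 28527448) had 0.555 ± 0.095 in control and 0.451 ± 0.107 in knockout cells (SD, n = 2 each), with knockout to control ratios of 0.846 and 0.770. Jag1 went in opposite directions in the replicates, with ratios of 1.07 and 0.622. Without knockout replicate 2 Jag1 was higher (log2 change 0.32) and the list's mean change was 0.04. With 1 library left out in turn, the log2 change of Wnt5a ranged from -0.54 to -0.06 and that of Dkk2 from -0.53 to -0.11.

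Osr1, a factor of mesenchymal progenitors from the list of developmental transcription factors (chromosome 12, 9574442 to 9581500), had 0.752 ± 0.121 in control and 0.626 ± 0.164 in knockout cells (SD, n = 2 each), with ratios of 0.885 and 0.766 in the replicates. Its log2 change was -0.28 ± 0.24 (SE; -0.54 to -0.01 with 1 library left out), and it did not pass limma. Grem1, an antagonist of bone morphogenetic proteins and the only gene of the chondrogenic and osteogenic list (chromosome 2, 113748675 to 113758648), had 0.618 ± 0.068 in control and 0.472 ± 0.090 in knockout cells (SD, n = 2 each), a log2 change of -0.39 ± 0.25 (SE; -0.58 to -0.20 with 1 library left out).

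Of the 6 fibrogenic genes tested, 5 were lower and 1 was higher in knockout cells (mean log2 change -0.08). Osr1, described above, is on this list too and is 1 of the 5. After quantile normalization or without control replicate 1, 3 were lower and 3 higher. Without knockout replicate 2, 4 were higher and 2 lower (mean log2 change 0.09). Pdgfra, a receptor that marks fibro-adipogenic progenitors, had 0.445 ± 0.0033 in control and 0.411 ± 0.032 in knockout cells (SD, n = 2 each). Pdgfrb, Col1a1 and Col1a2 had log2 changes of -0.07 ± 0.36, -0.08 ± 0.46 and -0.07 ± 0.58 (SE), and Timp1, an inhibitor of metalloproteinases, 0.14 ± 0.57. Leaving out 1 library gave -0.21 to 0.08 for Pdgfrb, -0.53 to 0.37 for Col1a1, -0.48 to 0.34 for Col1a2 and 0.02 to 0.26 for Timp1. When only points 11 to 31 were used, Col1a1, Col1a2 and Timp1 changed sign. The collagen-binding proteoglycan gene Dcn had too little signal to test. The list did not pass camera (adjusted p = 0.436, and 0.592 with an estimated correlation). In the list of senescence and inflammation, the chemokine gene Ccl7 (chromosome 11, 82045712 to 82047525) had the lowest mean change of all genes lower in both replicates, -1.32 ± 0.66 (SE), but at a low level of 0.044 ± 0.020 in control and 0.011 ± 0.0034 in knockout cells (SD, n = 2 each). Igfbp4 and Igfbp7 had log2 changes of 0.13 ± 0.46 and -0.07 ± 0.57 (SE), each of the opposite sign without knockout replicate 2 (-0.43 and 0.48), while Ccl2 had too little signal to test. This list's mean was -0.42 and its median -0.07, with a camera adjusted p of 0.312 (0.592 with an estimated correlation) and a fry p of 0.0440 (adjusted p = 0.220 over the 5 lists). Its unadjusted fry p over the settings with all libraries ranged from 0.00635 (background subtracted) to 0.554 (mean over points, block and Pax7 point removed). Cdh5, the endothelial cadherin and the only gene of the endothelial list, had a log2 change of 0.41 ± 0.51 (SE) and was lower instead when only points 11 to 31 were used. Fisher's exact tests of direction gave an adjusted p of 0.590 or more for each of the represented lists. In each of these lists 0 genes passed limma, also when adjusted over the list alone. No gene of the lists for serine and one-carbon metabolism, alpha-ketoglutarate and glutamine enzymes, cell cycle drivers, cell cycle inhibitors, Polycomb, Hox, adipogenic, immune or housekeeping genes was among the 273.

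**Figure D4:**
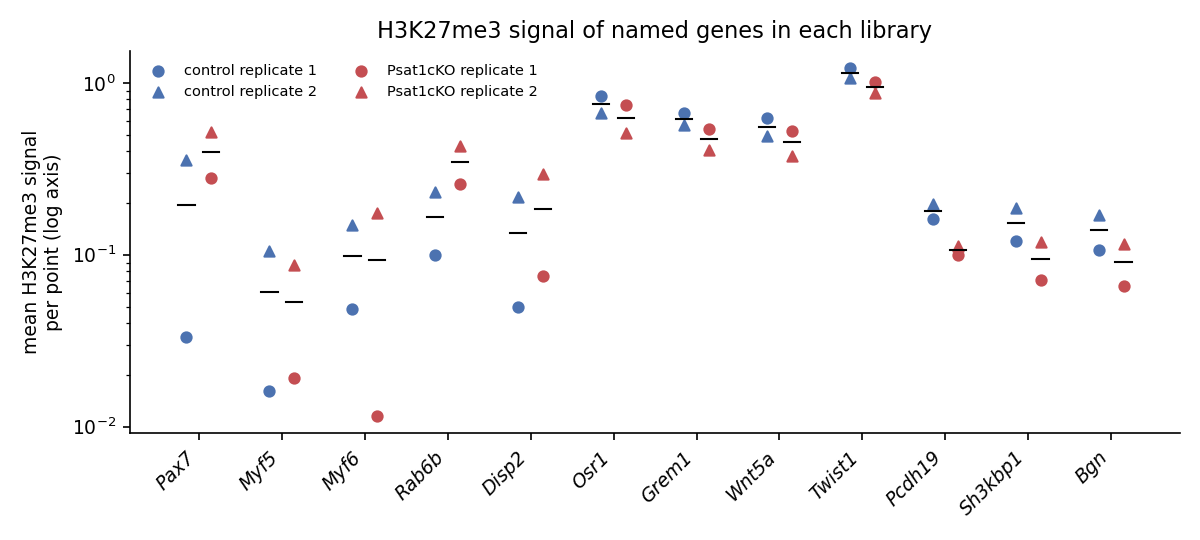
Mean H3K27me3 signal per point (vertical log axis) for 12 named genes in each library; circles are replicate 1, triangles replicate 2, and bars the mean of each genotype (n = 2). The control and knockout points of Pax7, Myf5 and Disp2 overlap, with replicate 2 above replicate 1, whereas both knockout points of Pcdh19 lie below both control points. Of the 218 genes tested, 23 (10.6%) had both knockout values below both control values, against 16.7% for a random order.

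Because 0 genes passed the test, the genes named next were chosen after their values were seen, as the 10 highest and 10 lowest mean changes among the 122 genes with the same direction in both replicates. Of the 10 highest, 7 were on the DOWN list. Rab6b, a small GTPase of vesicle transport (chromosome 9, 103111667 to 103185276), had 0.165 ± 0.093 in control and 0.344 ± 0.122 in knockout cells (SD, n = 2 each), with ratios of 2.58 and 1.86 and a log2 change of 1.08 ± 0.47 (SE; limma unadjusted p = 0.0440, adjusted p = 0.999; 0.51 to 1.65 with 1 library left out). Hsd11b1, which activates glucocorticoids, had ratios of 2.17 and 1.91 at a low level (0.022 ± 0.013 in control; SD, n = 2). Stac2, which binds muscle-type calcium channels, had ratios of 2.05 and 1.25. The ratios were 1.51 and 1.35 for Disp2, 1.80 and 1.13 for Palm3, 1.92 and 1.68 for Ldlrad4, and 1.56 and 1.35 for Camk1d; Pax7 and Cdh5 also belonged to this group. Without control replicate 1, Stac2, Disp2 and Palm3 were lower in knockout cells, and without knockout replicate 2 Disp2 was. With 1 library left out, the log2 change ranged from 0.32 to 1.17 for Hsd11b1, 0.44 to 0.83 for Ldlrad4, 0.19 to 0.67 for Camk1d and 0.13 to 0.68 for Cdh5.

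Of the 10 lowest, 8 were on the UP list and 5 on the X chromosome. Eva1b (chromosome 4, 126145709 to 126149875) had 0.267 ± 0.184 in control and 0.145 ± 0.078 in knockout cells (SD, n = 2 each), with ratios of 0.504 and 0.661. Dock5, an exchange factor for Rac, had ratios of 0.716 and 0.520, Gpnmb, a transmembrane glycoprotein, 0.686 and 0.551, and Efemp1, an extracellular matrix protein, 0.877 and 0.467. The X-linked genes were Pcdh19, a protocadherin (133582860 to 133689044; ratios 0.623 and 0.571), Col4a5, a basement membrane collagen (0.477 and 0.693), Sh3kbp1, an adaptor protein (0.590 and 0.633), Bgn, the proteoglycan biglycan (0.617 and 0.675), and Tceal5 (0.374 and 0.989). The direction turned for Efemp1 without knockout replicate 2 (log2 change 0.20), for Gpnmb without control replicate 2 (0.11) and for Tceal5 without knockout replicate 1 (0.21), while Eva1b was at -0.02 without control replicate 1 and Col4a5 at -0.06 without knockout replicate 1. With 1 library left out, Sh3kbp1 ranged from -0.98 to -0.33 and Bgn from -0.94 to -0.21. Pcdh19 had 0.179 ± 0.025 in control and 0.106 ± 0.0082 in knockout cells (SD, n = 2 each; log2 change -0.70 ± 0.41, SE; limma adjusted p = 0.999).

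By position, the 273 genes lay on 19 autosomes and the X chromosome, with 26 on chromosome 2, 25 on chromosome 7 and 9 on X, and as no gene was called, no class of higher and lower genes could be compared. Upstream of the start (points 1 to 20) the UP list had 0.196 ± 0.016 in control and 0.187 ± 0.0038 in knockout cells, and along the gene (points 21 to 81) 0.126 ± 0.0072 and 0.116 ± 0.016 (SD, n = 2 each). The DOWN list had 0.198 ± 0.099 and 0.226 ± 0.098 upstream, and 0.127 ± 0.050 and 0.142 ± 0.051 along the gene (SD, n = 2 each). The knockout to control ratio of the DOWN list was above 1 in both parts and both replicates, from 1.10 to 1.23. The ratio along the gene in replicate 1, 1.17, includes the single extreme point of Pax7 in the knockout library, which raises it.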

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

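Alternatives with the mean over points, background subtraction, the Pax7 point removed (also without control replicate 2, and with the mean and the block) and the block without sex chromosomes were chosen after seeing the data, the others before. The count of genes past the threshold was 0 under all but 3 of the settings run. It was 1 (Pax7) without control replicate 2, and 0 there once the Pax7 point was removed, so leaving out 1 library gave 0 to 1, and 4 with the mean over points and the replicate block: Pax7 and Rab6b higher (adjusted p = 0.00153 each, limma), and 2 genes lower, among them Twist1 (adjusted p = 0.00133, limma), a mesenchymal factor named after its values were seen. The Pax7 value there includes its single extreme point; without the point the count was 3, with Pax7 lost (adjusted p = 0.171, limma) and the other 3 genes kept (Rab6b adjusted p = 0.00131, limma). The cause was not tested. Smallest adjusted p-values ranged from 0.000114 to 1.00 over these settings. The labels do not say that a replicate number marks a shared batch, so the replicate block stands only here: with it the count stayed 0 (4 higher and 11 lower at an unadjusted p below 0.05, smallest adjusted p = 0.653, limma), although deviations from the genotype means of same-numbered libraries correlated at 0.758 across genes. For the X-linked genes described below, the block gave fry p = 0.0504, and camera p = 0.150 at an estimated correlation of -0.07. The share of genes with the same direction in both replicates moved from 56% to 65% above the median signal. The difference between the DOWN and UP list means, 0.23, ranged from -0.30 (without knockout replicate 2) to 0.80 (without knockout replicate 1); it was -0.25 without control replicate 1 and 0.75 without control replicate 2. Leaving out 1 library sets unequal mixtures of replicates against each other, and the lists differ between replicates. With an estimated correlation the difference of 0.23 was no longer past the threshold (p = 0.367, camera). In the other settings with all libraries it lay between 0.03 and 0.29. Its low end came with the mean over points, where the pseudocount shrinks all log2 changes. In all these settings the difference passed camera at the preset correlation, but in none of them at an estimated one (camera p = 0.135 to 0.547). For the DOWN list the unadjusted fry p ranged over these settings from 0.00965 (mean over points, block and Pax7 point removed) to 0.876 (background subtracted). For the UP list it ranged from 0.455 to 0.865. The number of fixed lists past camera was 0 in the main setting. The mean change of the myogenic regulators was -0.79 without control replicate 1 and 1.28 without knockout replicate 1, values that also carry their difference between replicates. A fit that leaves out 1 library assumes that the lone library of its genotype varies like the others. Requiring genes of at least 1 kb removed none of those tested. The median log2 change of all genes, -0.04, ranged from -0.17 to 0.09 when 1 library was left out, beyond the medians of the replicates (0.06 and -0.15) at both ends and changing sign; each shift was below 0.15, the SD of those medians. Of 39 tested genes looked at singly, 18 changed sign when some library was left out, 7 under another setting, and 19 under none. Not run: ratios to IgG, promoter widths, overlaps of regions between tables and means over several regions of a gene, since the values used hold 1 profile for the same genes in each table, and count-based normalizations. Depth limits genes of low signal: 56.5 to 64.3% of the points of a library were at or near 0.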

Other observations

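All tests in this part were chosen after the patterns were seen. The replicates differed in which genes carried H3K27me3, alike in both genotypes. All 6 genes of the myogenic and muscle structure lists had more signal in replicate 2 than in replicate 1 in both control and knockout cells, with medians of the log2 difference of 1.38 and 1.3. Myf5 was 6.49 times higher in control and 4.51 times higher in knockout cells, Disp2 4.38 and 3.92 times, and Stac2 3.90 and 2.39 times. Eva1b went the other way, at 0.344 and 0.451 times. Over whole lists, 34 of 53 DOWN genes were higher in replicate 2 in both genotypes and 7 lower in both, while 36 of 220 UP genes were higher and 135 lower.

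More background in replicate 1 would, in values scaled to depth, also lower all other signal there by a common factor, which subtracting a background does not undo but which would move both lists alike. With the background subtracted, the DOWN median exceeded the UP median by 0.8159 in control and 0.990 in knockout cells. Subtracting did not lower the DOWN medians, which went from 0.677 to 0.802 in control and from 0.518 to 0.756 in knockout cells. The gap was within the SD of the members (0.972 and 1.02), but that is the spread of single genes, not the error of a median. The error of the medians was not tested, so for the whole DOWN list background stays open. Among genes above the median signal the gap lay slightly beyond the SD (0.935 and 1.11, SD 0.888 and 0.956). The error of these medians was not tested either, and background left by an imperfect subtraction need not move genes of unequal signal alike. Background therefore stays open for these genes too. Background also stays open for the fall of the UP list. There, subtracting the estimate moved the median in control cells from -0.20 to -0.01 but left -0.2342 in knockout cells. Since 220 of the 273 genes are UP genes, the list enters its own background estimate, so the shift cannot show how much background there was. A hypothesis is that the cultures of replicate 2 may hold a smaller share of cells of myogenic state, in which muscle genes would be more often silenced. The muscle genes exceeded the 7 fibrogenic genes in this difference by 1.545 or more in both genotypes, but with background subtracted the fibrogenic median in control cells was 0.03, so the opposite movement that the hypothesis needs stays open, and donors or days are not recorded.

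Of the 8 X-linked genes tested, from both lists, Bgn, Col4a5, Pcdh19, Sh3kbp1, Capn6, Kcne1l and Tceal5 were lower in knockout cells in both replicates and Timp1 was higher, with median knockout to control ratios of 0.620 and 0.713, whereas 65 of 210 autosomal genes (31%) were lower in both (two-sided Fisher's exact p = 0.00204, across genes, which are not independent). The mean log2 change was -0.48 (camera p = 3.36e-05 with a preset correlation, p = 0.247 with an estimated one, fry p = 0.386). It was -0.74 without control replicate 1, -0.84 without knockout replicate 2, -0.21 without control replicate 2 and -0.12 without knockout replicate 1. Of 10000 autosomal sets drawn from the 20 genes nearest in signal to each X-linked gene, 0 had a median change as low. The lowest median drawn was -0.35, against -0.60 for the X-linked genes. The draws take genes as independent. Camera estimated a correlation of 0.94 between the X-linked genes, but in the fit without a replicate term. That estimate includes their shared difference between replicates, which drops out of changes taken within a replicate. Whether those changes are independent between the X-linked genes was not tested. The set was also picked after its values were seen, so the count does not measure how unlikely the pattern is. A candidate explanation is a smaller share of cells with an inactive X chromosome, which carries H3K27me3 over broad stretches, in the knockout cultures: points outside the gene were lower too, with a median of 0.7248 for the ratio averaged over the replicates and all 8 genes below 1 in that average (Kcne1l was at 1.02 in replicate 2), though these points are part of the sums in which the pattern was seen. They also include points 1 to 20, which hold part of the signal peak around the start. A loss local to each gene would lower those points as well, so the check cannot separate it from a loss over broad stretches. X-linked signal also differed between replicates of a genotype, replicate 2 being 1.55 times replicate 1 in control and 1.57 times in knockout cells; the sex of the animals is not given in the sources used here, and an effect of Psat1 loss on these genes stays open as untested.

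At point 60 of Pax7, inside the gene, knockout replicate 1 had a signal of 20.9, worth 197 reads at the inferred depth, where the highest value at any other point of any gene in the tables was 4.14. A broad H3K27me3 domain would raise the neighbouring points, but the mean of the adjoining points was 0.005087 of the point. DNA carried by both knockout libraries, such as the Cre allele at Pax7, should appear in both, but the value in knockout replicate 2 was 0 of that in replicate 1 after rounding. What stays open is a local pile of reads in this library, from amplification or foreign DNA, which could only be read from the alignments; no biological explanation was tested. Removing the point left the mean change of the DOWN list at 0.14 in place of 0.16, that of the myogenic regulators at 0.03 in place of 0.32, and that of Pax7 at 0.76 in place of 1.63. Apart from the point, the signal of Pax7 lay mainly in points 1 to 30, at 0.803 in control replicate 2 and 1.16 in knockout replicate 2, against 0.068 and 0.154 in replicate 1.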
